A study of Mus musculus with 21 samples.

How the data were processed

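The series held 21 samples: 8 gene expression libraries per sorted fraction, 3 B cell receptor libraries and 2 hashtag libraries. The libraries came from pooled draining lymph node cells of 6 mice, 2 for each of days 10, 16 and 22. The files used here were the gene list, the cell names, the count matrix and the cell table. The receptor sequences were not used here, so receptor mutation and clones were not analysed here. Per the labels, the authors processed the reads with Cell Ranger and Seurat against the mouse genome mm10/GRCm38, and versions are not stated.

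The deposited matrix gives raw UMI counts (unit: count) for 14493 genes in 6619 cells, and its sums equalled the total in the deposited cell table in all 6619 cells. The deposited cell table also gives module scores (unit: score) per cell, a phase call, cluster numbers, the state as the authors named it, the day and the mouse. The rule for the states, the method of the phase call and the treatment of droplets holding more than 1 cell are not stated. No cell was removed here: the shallowest held 1335 UMIs and 763 genes, and 0 cells had under 1000 UMIs. Doublet scores (scrublet in scanpy 1.11.5) called 2 of 6183 cells of the non-PC fraction and 3 of 436 of the PC fraction, and were not used to remove cells. With so few calls the scores say little on doublets. Of the prePC cells 1 of 10 was called in the PC well and 0 of 37 in the other, and the 10 had the highest median score of any state and well (0.0941, against 0.0290 to 0.0724). Intervals and floors cover counting error only.

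The mouse was the replicate. Counts were summed per mouse and population, leaving out sums of fewer than 10 cells. For prePC cells the minimum was 3 cells, chosen after the data were seen, because 10 left 1 mouse. Sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM library sizes, filterByExpr) in R 4.3.3, with the mouse as a block where 2 populations of the same mice were compared. The days were compared over all 3 and in pairs. These fits share information on spread between genes, so a very small p does not measure the spread between mice alone. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 differences are given with their SE, and mean CPM (counts scaled to a common library size) with the SD over mice.

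The 28 gene lists, the comparisons and the alternatives were fixed before the data were examined, except for those named as added. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and with an estimated correlation, and with fry. Genes were named by a rule: the 6 largest positive and the 6 largest negative log2 differences among genes past the threshold with at least 20 CPM in the higher population and the same direction in every mouse, without immunoglobulin, mitochondrial and predicted genes. Up to 4 members with the lowest p of each list described were added, and a gene named in 1 comparison was also allowed in the others. Not every gene the rule took is given. Where a population had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts it is a ratio of counts per UMI with an exact 95% interval. The 20 genes of the droplet test were the most abundant in PC, immunoglobulin genes left out, among those higher there by over 3 log2 units than in other cells of the PC fraction. Gene positions are from GENCODE release M21 of GRCm38.

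Shares of cells and of UMIs were compared over mice with 2-sided exact permutation tests, by sign changes within mice or by all pairings of mice with days, and adjusted within each family. The smallest p the 6 mice allow is 0.03125 for pairs. For proliferation every cell was thinned to 4727 UMIs, the 10th percentile of all cells, which left 5957 cells and removed 662 shallower ones. The edgeR fits were tested on simulated data with known changes of 2-fold and 4-fold. Between the fractions 77 of 100 and 99 of 100 of these were called, and between days 22 and 10 in the non-PC fraction 88 and 100 of 100. In the PC fraction the same days gave 6 of 100 and 60 of 99. False calls were 5 between the fractions, and 34 and 6 for these days in the non-PC and the PC fraction. Over 20 further draws false calls made up 5.28%, 8.35% and 9.97% of the calls on average (8.21% and 5.04% for prePC against germinal centre cells and PC, 5.42% between the zones, 6.32% for cycling PC and 9.32% for preMem). These averages lie above the 5% of the threshold, by least for prePC against PC and by most for the days in the PC fraction.

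The alternatives were DESeq2 size factors, DESeq2's own test (1.42.0), no filter on low counts, at least 30 cells per sum, no immunoglobulin genes (253), cells thinned before summing, no mouse block, cells named against their fraction left out, and each mouse left out in turn. Shares were recomputed with other denominators, definitions and weights. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for shares and plots. All cells of a fraction shared its capture, so a day was not confounded with a library, whereas fraction and capture could not be separated.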

Results

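The data were single-cell gene expression counts from lymph node B cells that had passed through the germinal centre response, the site where B cells mutate their receptors and are selected. Mice were immunised under the skin with 100 µg of the hapten carrier NP-KLH, and tamoxifen (5 mg) switched on the yellow fluorescent protein eYFP in responding B cells. Draining nodes were taken on days 10, 16 and 22 of the primary response from 2 mice per day, so 6 mice in all. The IgD-negative, eYFP-positive cells of each mouse were sorted into a plasma cell (PC) fraction and a non-PC fraction, tagged by mouse, and pooled by fraction before capture. The cell table held 6619 cells and 14493 genes, with 436 cells of the PC fraction and 6183 of the non-PC fraction.

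The depth differed between mice and fractions. For the PC fraction the totals were 343838 and 2985833 UMIs in day 10 mice 1 and 2, 606156 and 1501273 in the day 16 mice, and 921233 and 540791 in the day 22 mice. For the non-PC fraction they were 5917047 and 15613386, then 6588026 and 9916280, then 13233114 and 10706079. Single cells held 1335 to 70744 UMIs. The authors' annotation put 3194 cells in the light zone state (LZ), 2382 in the dark zone state (DZ), 232 in a state between them (LZtoDZ), 522 in a memory precursor state (preMem), 47 in a plasma cell precursor state (prePC) and 242 in PC. The prePC cells numbered 3 and 28 in the day 10 mice, 0 and 5 in the day 16 mice, and 5 and 6 in the day 22 mice.

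The PC fraction was a mixture: 202 of its 436 cells were named as another state. PC made up 53.3% ± 31.6 (SD, n = 6 mice) of the PC fraction and 0.136% ± 0.0724 of the non-PC fraction. LZ cells made up 17.7% ± 14.0 and 50.9% ± 3.77, and DZ cells 7.99% ± 6.87 and 38.2% ± 5.91. LZtoDZ cells were 10.2% ± 7.24 of the PC fraction and 2.89% ± 0.709 of the non-PC fraction, higher in 5 of 6 mice (exact p = 0.0938, adjusted p = 0.141). PreMem cells were 7.99% ± 6.83 and 7.33% ± 6.06, and prePC cells 2.76% ± 2.83 and 0.49% ± 0.583. With 6 pairs the smallest p of the 2-sided exact permutation test is 0.03125. PC, LZ and DZ reached it with all 6 mice in 1 direction, and their adjusted p over the 6 states was 0.0625, so no share passed the correction.

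**Figure D1:**
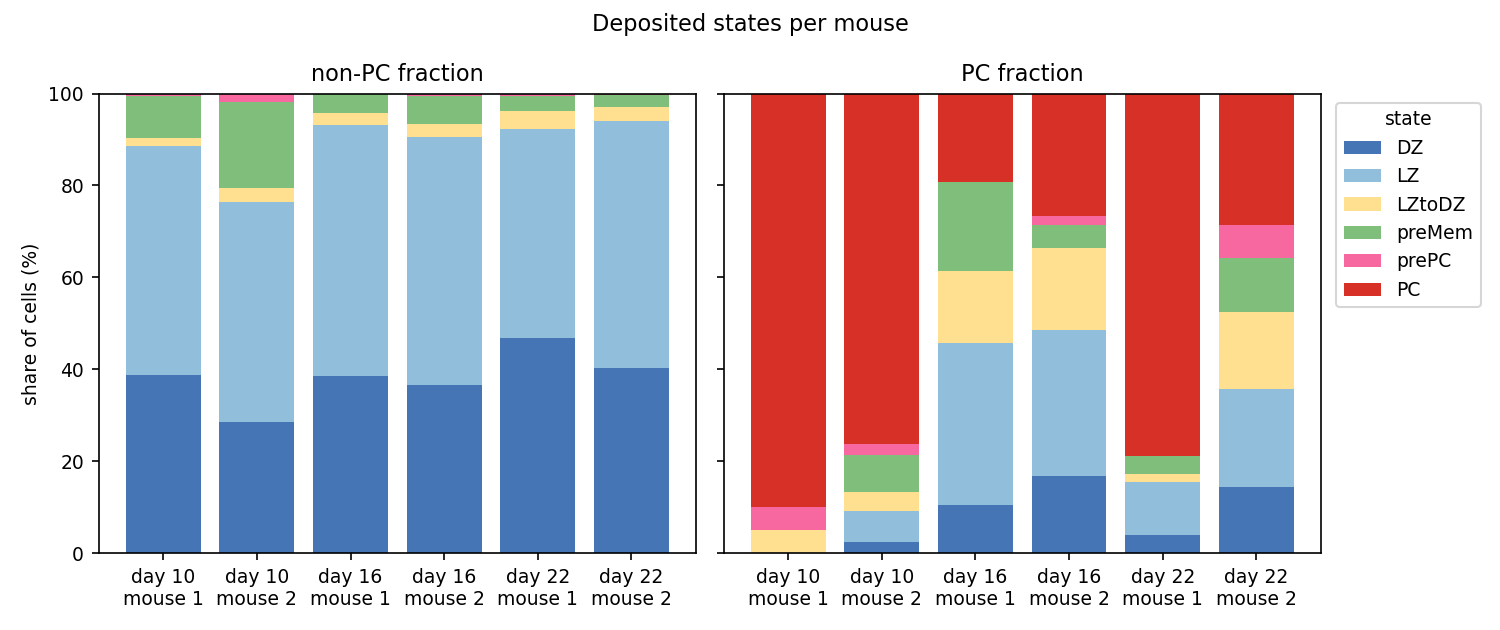
Share of cells (%) in each deposited state for each of the 6 mice, stacked to 100%, in the non-PC fraction (left) and the PC fraction (right). PC were 0.136% of the non-PC fraction on average and 53.3% of the PC fraction, where they ranged from 19.3% to 90.0% between mice.

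Comparing the PC and non-PC fractions asks which programmes the sorted plasma cells carried that the other responding B cells did not. All 15 tested genes of the plasma cell identity list were higher in the PC fraction, by a median of 4.37 on the log2 scale, with 15 also when adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). The costimulatory receptor gene Cd28 (chromosome 1, 60716800 to 60773359, GRCm38) stood at 98.4 ± 60.9 CPM against 0.133 ± 0.186 (SD, n = 6 mice), a log2 difference of 9.10 ± 0.30 (SE; adjusted p = 1.3e-09). Sdc1, which encodes the plasma cell surface marker CD138 (chromosome 12, 8771323 to 8793715), was higher by 7.36 ± 0.29, the plasma cell transcription factor gene Prdm1 by 5.14 ± 0.27, and Tnfrsf17, the BCMA receptor gene, by 7.65 ± 0.36. All 27 tested genes of the endoplasmic reticulum and secretion list were higher (27 adjusted over the list alone, median 2.73; adjusted p = 0.22 with an estimated correlation). Among them were the chaperone gene Fkbp11 (chromosome 15, 98724366 to 98728198; 8.79 ± 0.34, 325 against 0.691 CPM), Hyou1 (2.73 ± 0.28), Dnajb9 (3.16 ± 0.32) and Sdf2l1 (3.13 ± 0.29).

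B cell genes were lower in the PC fraction. In the B cell identity list 13 of 17 genes were lower (16 adjusted over the list alone, median −1.39; adjusted p = 0.305 with an estimated correlation), among them Cd79b (−0.98 ± 0.14), Irf8 (−1.39 ± 0.24) and Swap70 (−1.15 ± 0.18). The germinal centre list had 13 of 14 genes lower (13 adjusted over the list alone, median −1.42; adjusted p = 0.305 with an estimated correlation), among them Fas (−1.09 ± 0.12), Gna13 (−0.79 ± 0.13) and Nuggc (−1.48 ± 0.23). MHC class II had 9 of 11 genes lower (10 adjusted over the list alone, median −0.95; adjusted p = 0.26 with an estimated correlation), among them H2-Ab1 (−0.55 ± 0.08) and Cd74 (−0.93 ± 0.13). B cell receptor signalling had 12 of 15 lower (13 adjusted over the list alone, median −1.16; adjusted p = 0.22 with an estimated correlation), with Lyn at −1.59 ± 0.19. The light zone list had 10 lower and 1 higher of 18 (10 and 1 adjusted over the list alone, median −0.85), and the dark zone list 3 lower of 6 (3 adjusted over the list alone, median −0.98), each with adjusted p = 0.22 with an estimated correlation.

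Biosynthesis genes were higher gene by gene in the PC fraction, and none of their lists kept its call with an estimated correlation. Of the 436 cells of this fraction 202 were not named PC. The Myc response and ribosome biogenesis list had 17 of 24 genes higher (17 adjusted over the list alone, median 0.42; adjusted p = 0.17 with an estimated correlation), with Mif at 1.03 ± 0.09 and the spermidine synthase gene Srm at 2.13 ± 0.19. Without cells named against their fraction that list had 6 genes higher and 3 lower (median 0.04), and glycolysis 2 and 3 (median −0.02). Such values are not given here for the other lists of this paragraph. Over 4 mice Mif was at 714 CPM in PC, 686 in germinal centre cells of the non-PC well and 1658 in those of the PC well. Srm was at 242, 74.9 and 212 CPM. The rise of Mif is thus not told apart from the other cells of the PC fraction. Amino acid and one-carbon metabolism had 8 of 11 higher (8 adjusted over the list alone, median 0.80; adjusted p = 0.17 with an estimated correlation), among them Phgdh (1.20 ± 0.10) and the transporter gene Slc7a5 (1.69 ± 0.21). Oxidative phosphorylation had 12 of 17 higher (12 adjusted over the list alone, median 0.48; adjusted p = 0.22 with an estimated correlation). Glycolysis had 6 higher and 1 lower of 12 (6 and 1 adjusted over the list alone, median 0.24; adjusted p = 0.17 with an estimated correlation). Migration and adhesion had 11 higher and 2 lower of 19 (12 and 2 adjusted over the list alone, median 0.91; adjusted p = 0.17 with an estimated correlation): the integrin genes Itgb7 (2.51) and Itga4 (2.40) were higher and the follicle homing receptor gene Cxcr5 (−1.34) was lower. Interferon response had 4 higher of 9 (4 adjusted over the list alone, median 0.58; adjusted p = 0.305 with an estimated correlation), among them Bst2 (3.30) and Isg20 (3.31). Of heavy chain constant genes 4 of 8 were higher and of light chain constant genes 4 of 4 (4 and 4 adjusted over each list alone, medians 3.22 and 2.23; adjusted p = 0.17 and 0.22 with an estimated correlation).

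Other lists moved little or both ways between the fractions. S phase had 4 genes higher and 5 lower of 24 (4 and 6 adjusted over the list alone), and G2 and M phase 3 lower of 25 (1 adjusted over the list alone). Memory B cell genes had 4 higher and 3 lower of 15 (7 and 4 adjusted over the list alone), survival and apoptosis 4 and 1 of 12 (4 and 3 adjusted over the list alone), and immediate early and handling stress 6 and 2 of 12 (6 and 2 adjusted over the list alone). Naive B cell markers had 2 higher and 3 lower of 8 (2 and 4 adjusted over the list alone), and mitochondrially encoded genes 1 and 1 of 13 (1 and 1 adjusted over the list alone). Of markers of other cell types, the T cell genes Lck (−1.65 ± 0.33) and Lat (−1.66 ± 0.59) were lower, as was the globin gene Hbb-bt (−1.20 ± 0.40). Lat was at −2.89 without day 16 mouse 1 and was not called without any other 1 mouse (−1.19 without day 10 mouse 2, and −1.54, −1.65, −1.51 and −1.56 without day 10 mouse 1, day 16 mouse 2 and day 22 mice 1 and 2). Hbb-bt was not called without day 10 mice 1 or 2 or day 16 mouse 2 (−1.16, −1.10 and −1.17). Myeloid markers had 1 higher of 5 (1 adjusted over the list alone), stromal and endothelial markers 0 of 2 at either level except 1 lower over the list alone, and no NK cell marker passed the filter for testing.

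Over all genes, 3454 of 9313 differed between the fractions by edgeR, 1787 higher in the PC fraction and 1667 lower, and 1660 differed when cells were thinned to the same number of UMIs. The genes with the largest folds outside the lists included Zfyve28, with 229 UMIs in the PC fraction against 2 in the deeper non-PC fraction (1028-fold per UMI, counting interval 282 to 8544), and Hid1 with 109 against 1 (979-fold, 172 to 39024). In the plasma cell identity list the surface antigen gene Ly6c2 stood at 8.89 ± 0.68. The largest decreases outside the lists were in the actin-severing protein gene Gsn (−3.01 ± 0.49), the cytokine gene Lta (−2.63 ± 0.40), H1fx (−2.54), Haao (−2.51) and the lipase gene Lipc (−2.51).

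With camera at its preset correlation 16 lists differed between the fractions, and none did with an estimated correlation. The fry test, which asks whether the genes of a set move one way on balance and does not compare the set with other genes, gave adjusted p = 7e-04 for plasma cell identity and 0.0106 for B cell identity. When cells named against their fraction were left out, 1887 genes were higher and 2581 lower, and plasma cell identity had adjusted p = 0.0078 with an estimated correlation.

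Comparing prePC cells with germinal centre B cells (DZ, LZ and LZtoDZ) asks what separated the annotated precursors from the cells around them. Genes of recirculating and memory B cells stood higher in prePC cells. Of the 47 prePC cells, 28 were in the deposited cluster that held 473 of the 522 preMem cells. The median memory score of all prePC cells was 0.809, against 0.870 in preMem, 0.594 in LZ and 0.516 in DZ cells. Plac8 (chromosome 5, 100553725 to 100572245) was at 809 ± 479 CPM against 2.70 ± 1.66 (SD, n = 5 mice), a log2 difference of 8.19 ± 0.27 (SE; edgeR adjusted p = 8.4e-117). The fit shares information on spread between genes, so a p this small does not measure the spread of Plac8 between the 5 mice. Swapping the 2 sums within some of the mice still called up to 186 genes in this comparison. S100a10 was higher by 7.37 ± 0.30, the transcription factor gene Bhlhe41 by 8.43 ± 0.57 and the urokinase receptor gene Plaur by 6.92 ± 0.45. Upb1 had 27 UMIs in prePC cells against 1 in germinal centre cells (1544-fold per UMI, counting interval 255 to 63232).

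The memory list had 8 genes higher and 2 lower of 12 (8 and 2 adjusted over the list alone, median 2.60; adjusted p = 0.19 with an estimated correlation), including Klf2 (3.94), S1pr1 (4.30) and Ccr6 (4.07). Migration and adhesion had 11 higher and 1 lower of 17 (11 and 3 adjusted over the list alone, median 2.24; adjusted p = 0.19 with an estimated correlation), with Itgb7 at 4.89 and Vim at 2.24. Naive B cell markers had 3 higher and 1 lower of 8 (4 and 1 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation), Ccr7 at 4.59. Secretion genes had 14 of 26 higher (17 adjusted over the list alone, median 0.81; adjusted p = 0.18 with an estimated correlation), including Hsp90b1 (2.03 ± 0.19), Pdia4 (2.48) and Manf (1.52). Plasma cell identity had 4 of 9 higher (5 adjusted over the list alone, median 0.39; adjusted p = 0.29 with an estimated correlation): Irf4 (2.29 ± 0.48), Xbp1 (1.06 ± 0.23), Fam46c (1.74) and Jchain (0.85 ± 0.12). Without day 10 mouse 2 Irf4 and Fam46c were not called (2.21 and 1.41). The PC well gave 10 prePC cells and the other 37, against 156 and 5652 germinal centre cells. Between the wells, germinal centre cells of the PC well had higher Hsp90b1 (0.99) but not Jchain (−0.12) or Mzb1 (−0.24). A part of the well in the rise of secretion and plasma cell genes is thus not told apart. Interferon response had 5 of 7 higher (5 adjusted over the list alone, median 1.34; adjusted p = 0.19 with an estimated correlation), Isg15 at 1.97 and Ifi27l2a at 1.61.

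All 14 germinal centre genes were lower in prePC cells (14 adjusted over the list alone, median −1.67; adjusted p = 0.15 with an estimated correlation), including Nuggc (−2.66) and the base excision repair gene Neil1 (−2.17). The B cell identity list had 9 lower and 1 higher of 17 (9 and 1 adjusted over the list alone, median −0.63; adjusted p = 0.48 with an estimated correlation), with the repressor gene Bach2 at −2.58, Ebf1 at −1.11 and Cd79b at −0.76. Cpne5 (−3.80 ± 0.57) and the ephrin gene Efnb1 (−2.89 ± 0.45) were also lower. Hbb-bt had 0 UMIs in prePC cells, at least 7.24-fold lower than in germinal centre cells (floor of 3 counts over the group), and 2 myeloid markers, Tyrobp and Cd68, were higher. Neither was called without day 10 mouse 2 (0.68 and 1.44).

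In all, 729 of 8631 genes differed by edgeR, 312 higher and 417 lower, over 5 mice with at least 3 prePC cells. With DESeq2's test there were 411, with thinned cells 223, and without day 10 mouse 2, which held 28 of the 47 prePC cells, 314. Changes of 2-fold were mostly out of reach in this comparison: 10 of 100 such changes added to simulated counts were called, against 84 of 100 changes of 4-fold.

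Against PC, prePC cells had higher B cell genes and lower secretion genes. Of the 47 prePC cells 37 came from the non-PC well, and of the 242 PC 234 came from the PC well. State and well are thus largely not told apart in this comparison. All 10 tested B cell identity genes were higher (10 adjusted over the list alone, median 2.45; adjusted p = 0.2 with an estimated correlation), among them Ebf1 (3.35). All 9 MHC class II genes were higher (9 adjusted over the list alone, median 1.61; adjusted p = 0.22 with an estimated correlation), with H2-Oa at 3.59. All 27 secretion genes were lower (27 adjusted over the list alone, median −2.48; adjusted p = 0.22 with an estimated correlation), including Fkbp11 (−5.15 ± 0.32), Manf (−2.64) and the signal peptidase gene Spcs1 (−2.63). Plasma cell identity had 12 of 13 lower (12 adjusted over the list alone, median −3.05; adjusted p = 0.19 with an estimated correlation), among them Xbp1 (−3.05 ± 0.21), Ly6c2 (−4.67 ± 0.46) and Cd28 (−4.52 ± 0.48). Heavy chain constant genes had 3 of 4 lower (4 adjusted over the list alone, median −4.74; adjusted p = 0.2 with an estimated correlation), with Ighg1 at −4.80. It was not called without mouse 2 of day 10, 16 or 22 (−4.86, −4.66 and −4.89).

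B cell receptor signalling had 9 of 12 higher in prePC cells than in PC (10 and 1 lower adjusted over the list alone; adjusted p = 0.22 with an estimated correlation). Oxidative phosphorylation had 6 of 17 lower (7 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation). The chemokine receptor gene Ccr6 had 95 UMIs in prePC cells against 3 in PC (160.0-fold per UMI, counting interval 53.1 to 789.6). Serpinb1a was higher by 6.34 ± 0.34, S100a6 by 4.55, Ncf1 by 4.43, Btg1 by 4.28 and the inhibitory receptor gene Cd22 by 4.18, and Trp53inp1 was lower (−4.16). Of 2832 genes tested, 445 were higher and 453 lower, 898 in all over 5 mice. The number was 435 with thinned cells, 1491 with no filter on low counts and 509 without day 10 mouse 2.

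**Figure D2:**
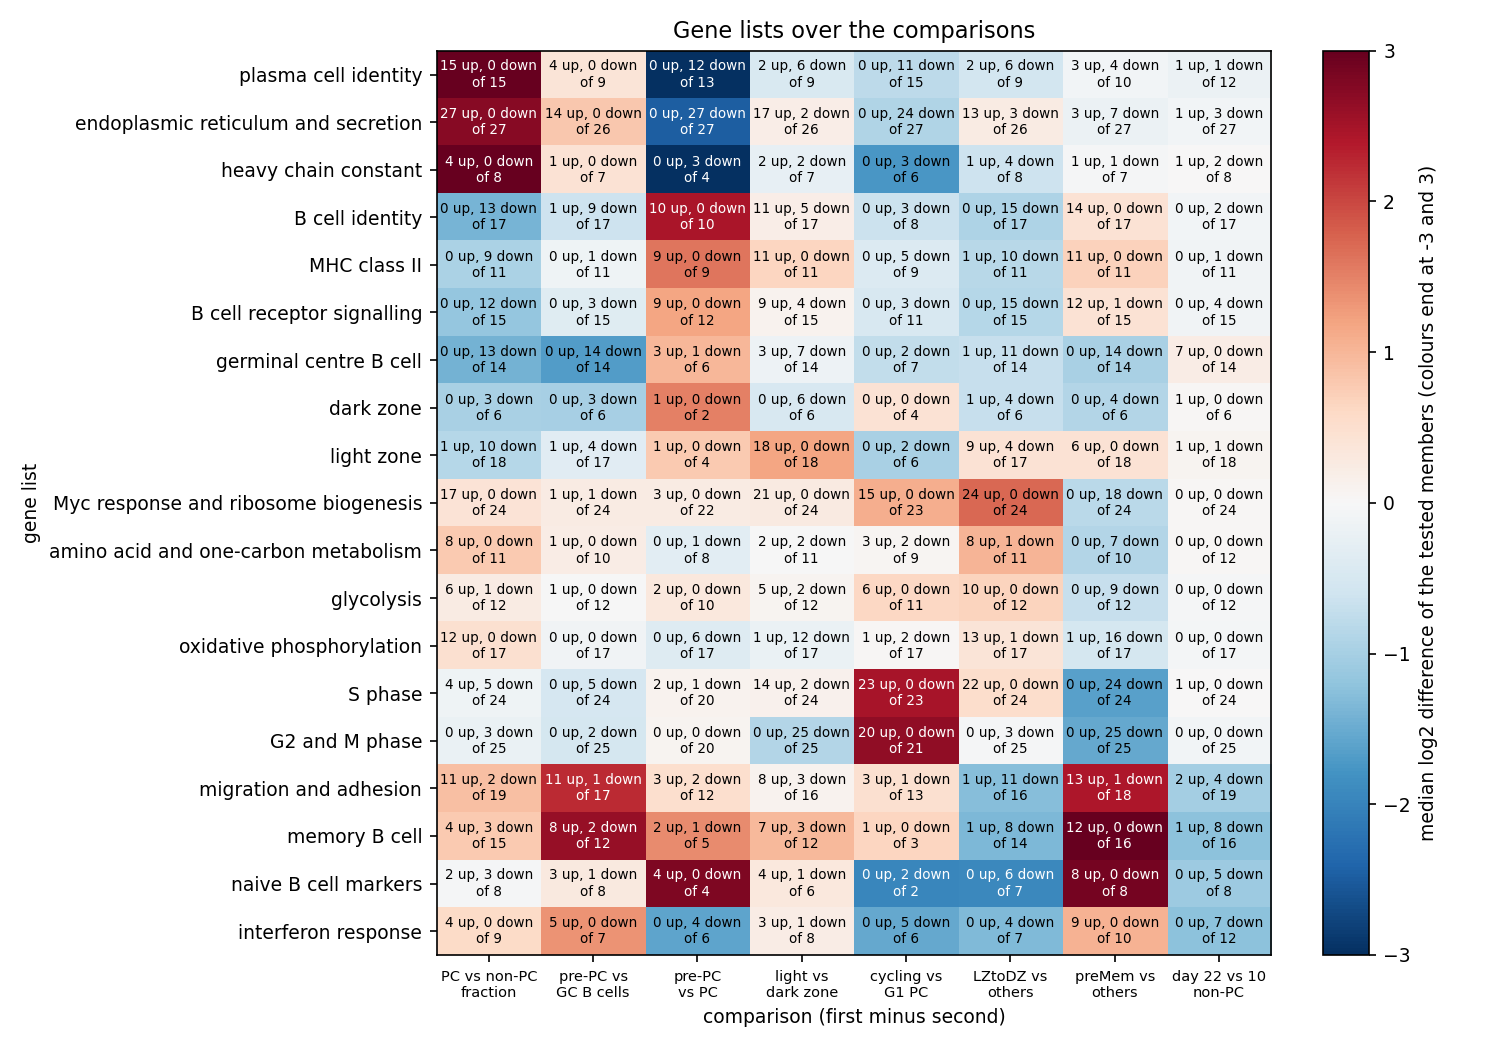
Median log2 difference (colour) of the tested members of 19 gene lists (vertical axis) over 8 comparisons (horizontal axis), with the number of members called higher and lower of those tested. Germinal centre genes were 0 higher and 14 lower of 14 in prePC against germinal centre B cells, and Myc response genes 24 higher of 24 in LZtoDZ cells.

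The comparison of LZ with DZ cells asks how the zones of selection and of division differed. All 18 light zone genes were higher in LZ (18 adjusted over the list alone, median 1.20) and all 6 dark zone genes lower (6 adjusted over the list alone, median −0.48), and both lists kept an adjusted p of 0.039 with an estimated correlation. The deposited cell table carries zone scores beside the state names, and how the names were assigned is not stated, so these lists may not be independent of them. The activation marker gene Cd83 (chromosome 13, 43784775 to 43803132) was at 500.2 ± 26.0 CPM in LZ and 111 ± 8.77 in DZ (2.18 ± 0.05; edgeR adjusted p = 4.8e-16, n = 6 mice), with Il4i1 (2.42 ± 0.07), Egr1 (1.54 ± 0.07), Cd86 (0.99 ± 0.05) and Slamf1 (0.96 ± 0.04) also higher. Rgcc, a cell cycle regulator (chromosome 14, 79288756 to 79301645), was at 53.3 ± 10.5 and 191 ± 29.2 CPM (−1.85 ± 0.05; adjusted p = 1e-31). Emp2 (chromosome 16, 10281749 to 10313968) was lower (−2.26 ± 0.11), with the chemokine receptor gene Cxcr4 at −1.08 ± 0.09 and the polymerase gene Polh at −1.30.

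All 25 G2 and M phase genes were lower in LZ (25 adjusted over the list alone, median −0.87; adjusted p = 0.11 with an estimated correlation), Cdc20 at −1.63, Cenpf at −1.40 and Ccnb1 at −1.40. S phase had 14 higher and 2 lower of 24 (14 and 2 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation). All 11 MHC class II genes were higher (11 adjusted over the list alone, median 0.65; adjusted p = 0.17 with an estimated correlation). So were 21 of 24 Myc response genes (21 adjusted over the list alone, median 0.28; adjusted p = 0.17 with an estimated correlation). Oxidative phosphorylation had 12 lower and 1 higher of 17 (12 and 1 adjusted over the list alone, median −0.19; adjusted p = 0.21 with an estimated correlation). Serpinb1a (2.39), Hivep3 (1.99), Ephx1 (1.88) and Snn (1.83) were among the other largest increases, and Scn8a (−1.78), Lmo4 (−1.63) and Cdkn3 (−1.60) among the decreases. T cell markers had 2 of 2 higher and myeloid markers 2 of 4 in LZ. In all 3373 of 9390 genes differed, 1652 higher and 1721 lower; DESeq2's test gave 1606 and thinned cells 2187.

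Each state was also set against the other cells of its fraction. The deposited cell table carries a memory score, a PC score and a score named ACT beside the state names. How the names were assigned is not stated, so lists of such programmes may not be independent of them. LZtoDZ cells stood out by growth genes: all 24 Myc response genes were higher (24 adjusted over the list alone, median 1.71; adjusted p = 0.13 with an estimated correlation), Srm (chromosome 4, 148591503 to 148594993) by 3.03 ± 0.08, C1qbp by 2.25, Mif by 1.97 and the nucleolar gene Npm1 by 1.72. S phase had 22 of 24 higher (22 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), and glycolysis 10 of 12 (10 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Ccnd2, which encodes the G1 cyclin D2, was higher by 3.61 ± 0.27, Tnfrsf8, which encodes CD30, by 4.67 ± 0.33, Smyd2 by 3.62 and Fabp5 by 3.18. All 15 B cell receptor signalling genes were lower (15 adjusted over the list alone, median −0.85; adjusted p = 0.15 with an estimated correlation), with Cd79b at −1.48. MHC class II had 10 lower and 1 higher of 11 (10 and 1 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), and Vim was at −3.13. In all 4593 of 8912 genes differed, 2235 higher and 2358 lower, and 2513 with thinned cells; LZtoDZ cells held a median of 22505 UMIs against 7784.5 in LZ and 9310 in DZ.

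PreMem cells carried memory and recirculation genes and little of the cell cycle. Their median memory score was 0.870, against 0.413 to 0.809 in the other states, so the memory list may restate the naming. Memory genes had 12 of 16 higher (12 adjusted over the list alone, median 3.37), migration 13 higher and 1 lower of 18 (13 and 1 adjusted over the list alone, median 2.44) and MHC class II 11 of 11 (11 adjusted over the list alone, median 0.70), each with an adjusted p of 0.043 with an estimated correlation. The quiescence factor gene Klf2 was higher by 5.01 ± 0.33, Ccr6 by 4.98, the oxysterol receptor gene Gpr183 by 4.25 and Hhex by 3.31. All 8 naive markers were higher (8 adjusted over the list alone, median 2.87; adjusted p = 0.035 with an estimated correlation), Ighd at 4.24 and Ccr7 at 4.86. All 24 S phase genes (24 adjusted over the list alone, median −1.62; adjusted p = 0.026 with an estimated correlation) and all 25 G2 and M phase genes (25 adjusted over the list alone, median −1.54; adjusted p = 0.035 with an estimated correlation) were lower, Rrm2 at −2.12. The asparagine synthetase gene Asns was at −2.75 and Rgcc at −2.71. In all 3171 of 9135 genes differed, 1417 higher and 1754 lower, and 1812 with thinned cells.

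The same test called 3765 of 9441 genes in DZ cells (1857 higher, 1908 lower) and 2601 of 9511 in LZ cells (1280 and 1321). DESeq2's test gave 2066 and 1102, and thinned cells 2399 and 1468. Within the PC fraction, PC differed from the remaining cells in 1826 of 4006 genes (910 and 916, 5 mice; 605 with thinned cells). Cd28 had 554 UMIs in PC and 0 in the others, at least 94.6-fold higher (floor of 3 counts over the group), while the B lineage factor gene Pax5 had 1 against 215 (420-fold lower per UMI, counting interval 74.5 to 16656). There 19 of 24 Myc response genes were lower and 1 higher in PC (19 and 1 adjusted over the list alone, median −0.75; adjusted p = 0.31 with an estimated correlation). LZ cells of the PC fraction differed from its other cells in 373 of 3634 genes (182 and 191, 3 mice), with Gsn at 3.04 ± 0.41 and Cd86 at 2.90 ± 0.46. Without day 16 mouse 2 that number was 67 and Cd86 was not called (2.84). It was 103 with thinned cells and 597 with no filter.

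Germinal centre cells captured in the PC well were compared with those of the non-PC well after the mixture had been seen. All but 2 of the 24 Myc response genes were higher in the PC well (22 higher, 22 adjusted over the list alone, median 0.91; adjusted p = 0.14 with an estimated correlation), C1qbp by 1.43 ± 0.08, Mif by 1.30 ± 0.05 and the nucleolin gene Ncl by 0.99 ± 0.06. B cell identity had 15 of 17 lower (16 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), Cd79b at −0.80 ± 0.05, and B cell receptor signalling 13 of 15 lower (14 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Ccnd2 was higher by 2.30 ± 0.43 and Gsn lower (−1.93 ± 0.16). LZtoDZ cells were 43 of 156 germinal centre cells in the PC well (27.6%, exact 95% interval 20.7 to 35.3) and 189 of 5652 in the other (3.34%, 2.89 to 3.85). Of 9042 genes 1893 differed over 4 mice, 936 higher and 957 lower; 580 did with thinned cells and 1006 with at least 30 cells per sum. Well and sort gate cannot be told apart here.

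Cycling PC (phase S or G2M by the deposited call) were compared with PC in G1 to ask whether division went with a change in the secretory programme. The division genes that define the groups were higher: 23 of 23 S phase and 20 of 21 G2 and M phase genes (23 and 21 adjusted over each list alone; adjusted p = 0.24 with an estimated correlation for both), which is circular. Nusap1 (chromosome 2, 119618298 to 119651244) was at 86.5 ± 37.0 CPM against 1.36 ± 2.35 (SD, n = 3 mice; 4.81 ± 0.49, edgeR adjusted p = 8.8e-08). Its 4 UMIs in G1 all came from day 10 mouse 2. Without that mouse it was still called (edgeR adjusted p = 0.0250), but G1 then held 0 UMIs, so no fold is given. Cdk1 was higher by 4.29 ± 0.35. Secretion genes were lower in cycling PC, 24 of 27 (25 adjusted over the list alone, median −0.91; adjusted p = 0.24 with an estimated correlation), including Hsp90b1 (−0.97 ± 0.04), Ssr4 (−1.60 ± 0.11) and Herpud1 (−2.03 ± 0.16). Plasma cell identity had 11 of 15 lower (11 adjusted over the list alone, median −0.79; adjusted p = 0.31 with an estimated correlation), with Xbp1 at −0.79 ± 0.12 and Ly6c2 at −1.62 ± 0.15.

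Of 6 heavy chain constant genes 3 were lower in cycling PC, Ighm (−1.89 ± 0.09), Ighe and Ighg3 (4 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). In PC of the 3 mice compared, Ighe had 828, 13 and 1 UMIs, and Ighg3 197, 31 and 5. They were the most abundant constant gene of 3 cells and 1 cell, all in day 10 mouse 2, so no fold is given for them. Interferon response had 5 of 6 lower (6 adjusted over the list alone, median −1.53; adjusted p = 0.24 with an estimated correlation), with Bst2 at −1.60 and Isg20 at −1.96. Immediate early genes had 7 of 9 lower (9 adjusted over the list alone, median −1.09; adjusted p = 0.24 with an estimated correlation), with Jun at −1.71 and Fos at −1.09. Myc response genes were higher, 15 of 23 (16 adjusted over the list alone, median 1.09; adjusted p = 0.31 with an estimated correlation), Ranbp1 at 1.91. So were 6 of 11 glycolysis genes (6 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), Ldha at 1.73. Il4i1 (−3.93), the stress response genes Ddit4 (−3.77) and Gadd45g (−3.24), and the lysosomal gene Cd68 (−3.40) were among the largest decreases. Apoc2 had 0 UMIs in cycling PC, at least 33.4-fold lower (floor of 3 counts over the group). In all 1010 of 3969 genes differed, 563 higher and 447 lower, over 3 mice. The number was 533 with DESeq2's test, 287 with thinned cells and 332 without day 10 mouse 2, where Fos (−1.08) was not called.

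The share of proliferating cells was read as cells with a UMI of the division genes Mki67 or Top2a after every cell was thinned to 4727 UMIs. It was 55.9% ± 16.5 in PC and 77.1% ± 0.896 in germinal centre cells (SD, n = 6 mice), lower in PC in 6 of 6 mice (difference −21.2 points, exact permutation p = 0.03125, adjusted p = 0.05 over 8 tests, not under the threshold). LZtoDZ cells had 86.5%, 11.3 points above LZ in 6 of 6 mice, and DZ cells 78.8% ± 1.51, 3.54 points above LZ (75.2% ± 1.48) in 6 of 6 mice, each with the same exact p and adjusted p. Immunoglobulin genes took 22.1% of PC UMIs, against 1.56% in DZ and 1.35% in LZ cells. Thinning to a common total thus left PC fewer UMIs of other genes, which lowers their share. PC minus germinal centre cells was −9.66 points without thinning (PC higher in 1 of 6 mice) and −5.59 by phase (3 of 6). It was −30.8 by cells with 2 or more UMIs over the G2 and M phase list after thinning (1 of 6). PrePC cells had 61.8% ± 12.9 over 4 mice. PreMem cells, of which 8.79% ± 3.10 were called S or G2M, had 55.9% ± 14.1. The first value is over all preMem cells. The second leaves out 203 of 522 preMem cells as too shallow to thin, against 2 of 242 PC. Against this preMem level, which was not tested as a background for this measure, the difference of PC was −0.0209 points (exact p = 1). It was 10.1 without thinning and 40.5 by phase, with PC higher in 5 of 6 mice by each, and −21.8 by cells with 2 or more UMIs over the G2 and M phase list (63.8% against 85.6%, higher in 1 of 6 mice). The preMem level differed between the wells: 186 of 302 preMem cells had a Mki67 or Top2a UMI after thinning in the non-PC well (61.6%, exact 95% interval 55.8 to 67.1) and 4 of 17 in the PC well (23.5%, 6.81 to 49.9). Of the PC captured in the PC well 132 of 232 had one (56.9%, 50.3 to 63.4). By these intervals, which cover counting error only, PC stood above the preMem cells of their own well and not above those of the other. The median depth before thinning was 18756 UMIs in PC, 6374 in preMem and 8992 in germinal centre cells, and free RNA in the wells stays open as a source of these UMIs. By the deposited phase 49.3% ± 25.6 of PC, 54.9% ± 3.92 of germinal centre cells and 41.2% ± 6.02 of prePC cells were in S or G2M, and no difference passed (lowest adjusted exact p = 0.1). No trend of the thinned share with day passed in 5 populations (PC r = 0.296, exact p = 0.556, adjusted p = 0.822).

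**Figure D3:**
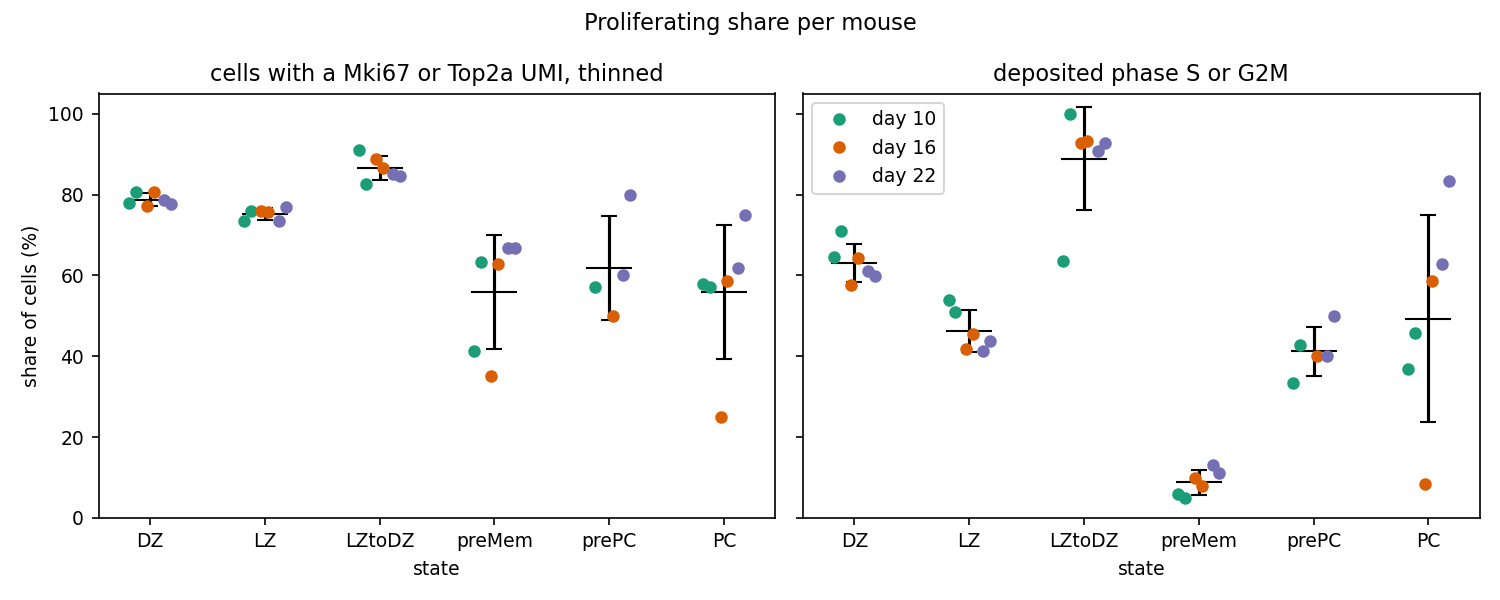
Share of cells (%) read as proliferating in each state, by a Mki67 or Top2a UMI after thinning (left) and by the deposited phase (right); points are mice with at least 3 cells, coloured by day, and bars the mean and SD. PC and preMem both averaged 55.9% by the first measure, but 49.3% and 8.79% by the second. The first measure leaves out 203 of 522 preMem cells and 2 of 242 PC as too shallow, and the second includes them.

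Heavy chain use differed between the fractions in every mouse for 4 genes. Ighg1, the IgG1 constant gene, made up 54.2% ± 18.7 of heavy chain constant UMIs in the PC fraction and 30.3% ± 5.08 in the non-PC fraction (SD, n = 6 mice), higher in 6 of 6 mice. Ighm, the IgM gene (chromosome 12, 113418558 to 113422730), made up 21.4% ± 7.58 and 52.5% ± 9.28, Ighd 0.399% ± 0.410 and 1.78% ± 0.760, and Igha 0.0788% ± 0.0345 and 1.64% ± 0.287, each lower in the PC fraction in 6 of 6 mice. The exact permutation p was 0.03125 for each, the smallest that 6 pairs allow, and the adjusted p over 8 genes was 0.0625. Ighg2c stood at 9.13% ± 10.7 and 1.59% ± 1.14, higher in 4 of 6 mice (exact p = 0.125, adjusted p = 0.167). Ighg2b (13.7% and 10.0%), Ighg3 (0.384% and 1.74%) and Ighe (0.647% and 0.372%) were split between mice. Counting each cell by its most abundant constant gene turned the difference for Ighd from −1.38 to 2.56 points.

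Within the non-PC fraction the IgM share was lower at each later day: Ighm was 63.1% ± 1.26, 52.0% ± 0.984 and 42.4% ± 0.0687 on days 10, 16 and 22 (SD, n = 2 mice per day). Its Pearson correlation with day was −0.996 (exact permutation p = 0.0222, adjusted p = 0.0593 over 8 genes) and Spearman's rho −0.956 (p = 0.0222); r was −0.995 without the day 10 mice and −0.990 without the day 22 mice. Ighg3 was 0.420%, 0.879% and 3.92% (r = 0.899, rho = 0.956, exact p = 0.0222 for both, adjusted p = 0.0593; r = 0.964 and 0.747 without the day 10 and the day 22 mice). Ighd was 2.59%, 1.60% and 1.15% (r = −0.846, rho = −0.956, exact p = 0.0222 for both, adjusted p = 0.0593; r = −0.984 and −0.761). PreMem cells, whose share was lower on later days, had 16.6% Ighd against 1.15% in germinal centre cells. Within germinal centre cells Ighd was 1.37%, 1.25% and 0.844% (r = −0.768, exact p = 0.0667). Counting each of these cells once gave 0.187%, 0.370% and 0.335% (r = 0.651), so the Ighd trend is not told apart from the mix of states. In the PC fraction Ighg1 was 76.2%, 48.7% and 37.6% (r = −0.922, exact p = 0.0444, adjusted p = 0.178; rho = −0.837, p = 0.0667; r = −0.661 and −0.927), and Ighe 1.65%, 0.253% and 0.0366% (r = −0.769, rho = −0.956, exact p = 0.0222 for both, adjusted p = 0.178; r = −0.757 and −0.771). For Ighe few cells carry this: it was the most abundant constant gene of 1 of 20 and 3 of 164 cells in the day 10 mice and of 0 cells in the other 4 mice. For Ighg1, counting each cell by its most abundant constant gene gave 66.7%, 40.7% and 40.7% (r = −0.852, and −0.00512 without the day 10 mice). By that count there was no further fall after day 16. The Ighg1 share of the non-PC fraction went the other way (25.6%, 32.0% and 33.4%; r = 0.687, exact p = 0.156, adjusted p = 0.178), and there Ighg2b (r = 0.808), Ighg2c (0.861) and Igha (0.797) had an exact p of 0.0444 each (adjusted p = 0.0593). None of these passed the correction, for which 0.0222 is the smallest p the 6 mice allow.

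**Figure D4:**
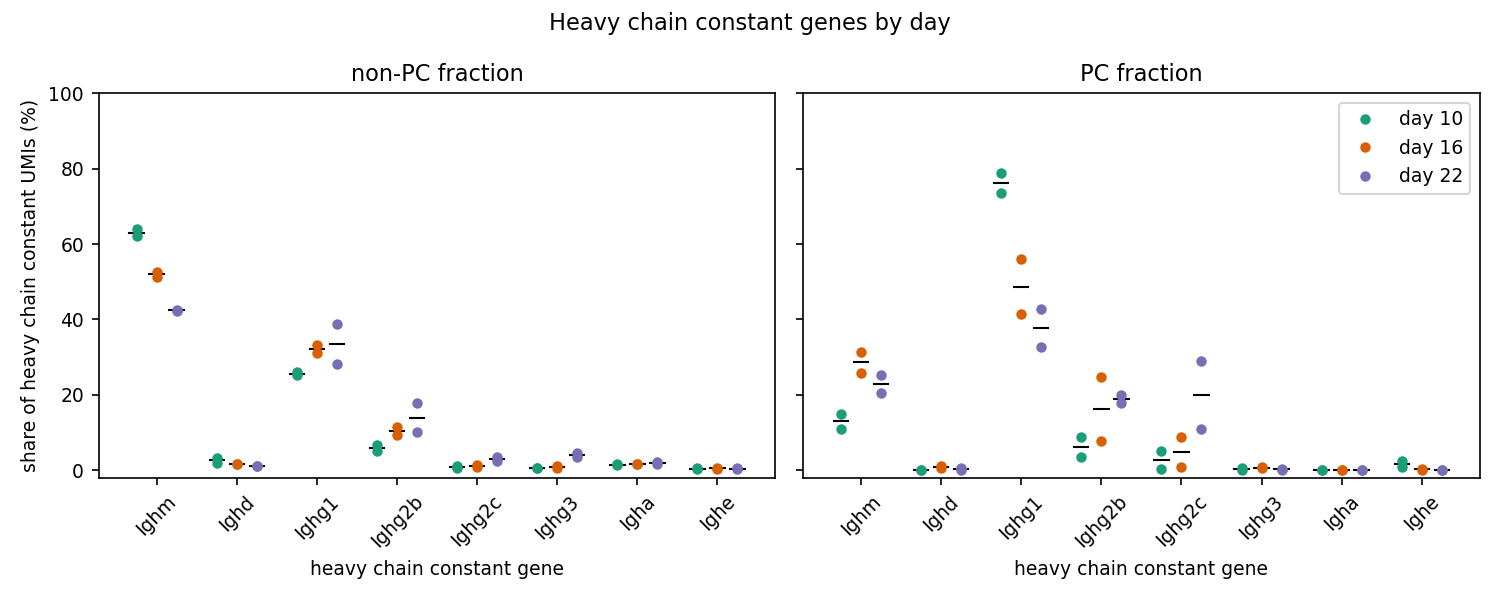
Share of heavy chain constant UMIs (%) of 8 constant genes in the non-PC fraction (left) and the PC fraction (right); points are mice coloured by day, and short lines the mean of the 2 mice of a day. The Ighm share of the non-PC fraction was 63.1%, 52.0% and 42.4% on days 10, 16 and 22.

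State shares differed between days in the same fraction without passing the correction over 6 states. PreMem cells made up 13.9% ± 6.87, 5.10% ± 1.40 and 2.99% ± 0.458 of the non-PC fraction on days 10, 16 and 22 (SD, n = 2 mice per day). Their correlation with day was r = −0.806 (exact permutation p = 0.0222, adjusted p = 0.133) and rho = −0.956 (p = 0.0222), with r = −0.820 without the day 10 mice and −0.782 without the day 22 mice. DZ cells made up 33.6%, 37.6% and 43.5% (r = 0.748, exact p = 0.111, adjusted p = 0.311; rho = 0.717, p = 0.178; r = 0.772 and 0.477). In the PC fraction PC made up 83.1%, 23.0% and 53.7% (r = −0.416, exact p = 0.4, adjusted p = 0.8; rho = −0.239, p = 0.711; r = 0.649 and −0.983).

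Gene expression of the non-PC fraction changed with day. Higher on day 22 than on day 10 were the membrane protein gene Emp2 (5.91 and 7.73 CPM in the day 10 mice, 36.9 and 28.8 in the day 22 mice; 2.22 ± 0.16, edgeR adjusted p = 3.1e-06), Osbpl3 (1.83 ± 0.16), Tox2 (1.77 ± 0.14), and the G protein signalling regulators Rgs13 (chromosome 1, 144138654 to 144177372; 1.22 ± 0.09) and Rgs10 (1.14 ± 0.08). Lower were Sdc4 (−2.50 ± 0.15), the galectin gene Lgals9 (chromosome 11, 78962974 to 78984946; −2.34 ± 0.13), Serpinb6b (−2.17), the interleukin 10 receptor gene Il10ra (−1.96) and Klf2 (−1.71). Klf2 was at 266 CPM in preMem cells against 8.20 in the other cells of this fraction. Since preMem cells were 13.9% of it on day 10 and 2.99% on day 22, the change of Klf2 is not told apart from the mix of states. In the germinal centre list 7 of 14 genes were higher (9 adjusted over the list alone, median 0.22; adjusted p = 0.22 with an estimated correlation), among them Mef2b (0.65), Klhl6 (0.52) and S1pr2 (0.37). Klf2 was not called without 1 of the day 16 mice (−1.70 for either) or the day 22 mice (−1.85 and −1.58), nor S1pr2 without day 10 mouse 2 (0.28).

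Interferon response genes were lower on day 22, 7 of 12 (11 adjusted over the list alone, median −1.23; adjusted p = 0.3 with an estimated correlation), including Irf7 (−1.06 ± 0.10), Bst2 (−1.05 ± 0.11), Oasl2 (−2.63 ± 0.33) and Rtp4 (−4.17 ± 0.53). On day 16 the same list had 7 of 12 lower than on day 10 (11 adjusted over the list alone, median −1.56; adjusted p = 0.23 with an estimated correlation). Memory genes had 8 lower and 1 higher of 16 on day 22 (10 and 1 adjusted over the list alone, median −1.24; adjusted p = 0.3 with an estimated correlation), S1pr1 at −1.60 and Cd38 at −1.35. Rtp4 was not called without day 16 mouse 1 or 2 (−4.18 and −4.17), nor Cd38 without day 22 mouse 1 (−1.32). Naive markers had 5 of 8 lower (7 adjusted over the list alone, median −1.09; adjusted p = 0.2 with an estimated correlation). These lists moved beside the share of preMem cells given above. Within LZ cells alone 6 of 10 interferon genes were lower on day 22 (8 adjusted over the list alone, median −0.83; adjusted p = 0.22 with an estimated correlation). Within DZ cells the number was 6 of 10 (8 adjusted over the list alone, median −1.23; adjusted p = 0.34 with an estimated correlation). Irf7 was lower in LZ (−0.77 ± 0.15) and in DZ cells (adjusted p = 3.1e-06), as was Lgals9 (−2.03 and −2.68). In LZ cells Irf7 was not called without mouse 2 of day 10 or 22 (−0.55 and −0.61).

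Over the 3 days 364 of 10521 genes differed in the non-PC fraction. Day 22 differed from day 10 in 545 genes (224 higher, 321 lower) and day 16 from day 10 in 161 (60 and 101). In simulated data false calls made up 8.35% and 8.20% of the calls of these 2 comparisons on average (20 draws), above the 5% of the threshold. The number for day 16 was 277 without day 10 mouse 1 and 57 and 65 without day 16 mice 1 and 2. Between days 22 and 16 there were 3 genes, Emp2 (1.07), Ighm (−0.43) and Ighv5-17 (−1.58), the last named after its value was seen; 550 had an unadjusted p under 0.05. Without 1 mouse there were more, 5 and 25 without day 22 mice 1 and 2, 11 and 8 without the day 10 mice, and 14 and 12 without the day 16 mice. Emp2 was not called without day 16 mice 1 or 2 or day 22 mouse 1 (1.15, 0.99 and 0.88), nor Ighv5-17 without a mouse of day 10 (−1.58 for either) or 16 (−1.60 and −1.55). The count over the 3 days was 193 without day 22 mouse 1 and 216 without day 10 mouse 2, and that of day 22 against day 10 was 166 and 303. With no filter on low counts these counts were 756 and 841. Within LZ cells 236 of 9726 genes differed over the days, and within DZ cells 131 of 9487; these comparisons were added to hold the state fixed. Thinned cells gave 153 and 82, DESeq2's test 125 and 78, and no filter 567 and 287. The lowest counts without 1 mouse were 100 in LZ (without day 22 mouse 1; 150 without day 22 mouse 2) and 76 in DZ (without day 10 mouse 2; 84 without day 22 mouse 1).

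**Figure D5:**
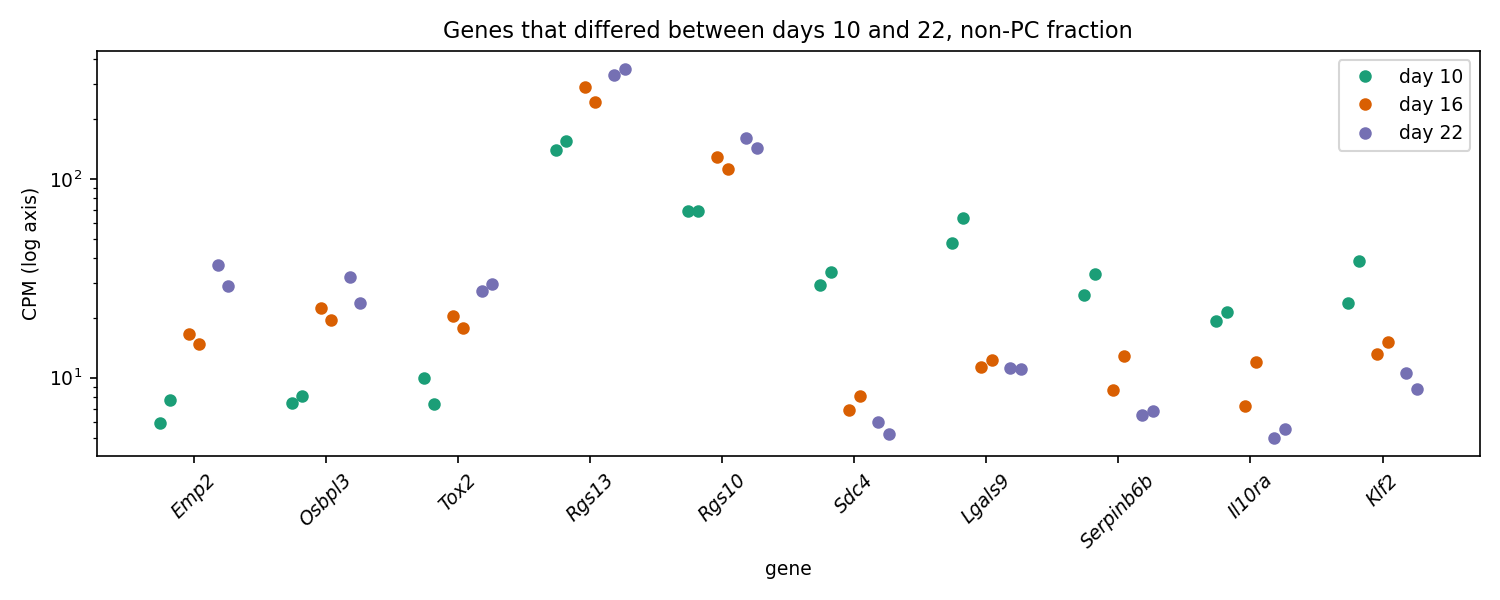
CPM (log axis) of genes named above from the comparison of day 22 with day 10 in the non-PC fraction; each point is 1 mouse, coloured by day. Emp2 was at 5.91 and 7.73 CPM on day 10 and at 36.9 and 28.8 CPM on day 22.

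In the PC fraction 76 of 5919 genes differed over the days, 276 between days 16 and 10 (43 higher, 233 lower). This last number was 98 and 27 without day 10 mice 1 and 2, 14 and 3 without the day 16 mice, and 917 and 913 without the day 22 mice. Secretion genes had 20 of 27 lower on day 16 than on day 10 (27 adjusted over the list alone, median −1.60; adjusted p = 0.35 with an estimated correlation), among them Ssr4 (−1.69 ± 0.20), Pdia4 (−2.08 ± 0.26) and Hspa5 (−1.43 ± 0.21), and plasma cell identity 6 of 15 (14 adjusted over the list alone, median −1.81; adjusted p = 0.35 with an estimated correlation), with Xbp1 at −1.81 ± 0.34. Without day 16 mouse 2 none of these 4 genes was called (−1.65, −1.91, −1.27 and −2.16). Nor were Ssr4 (−1.83) and Xbp1 (−1.60) without day 16 mouse 1, Hspa5 (−1.47) and Xbp1 (−1.76) without day 10 mouse 2, and Xbp1 (−1.87) without day 10 mouse 1. The share of this fraction named PC was 23.0% on day 16 and 83.1% on day 10, and with the cells not named PC left out, 4 genes differed over the days and 3 between days 16 and 10. The differences of Hspa5 and Ssr4 between days 16 and 10 were then 0.069 and 0.061, while Pdia4 and Xbp1 kept their direction. Days 22 and 10 differed in 3 genes, all immunoglobulin variable genes named after their values were seen; 278 had an unadjusted p under 0.05. Few cells carried them, so no fold is given. Ighv1-12 had 873 UMIs on day 10 (820 in 1 cell) and 3 on day 22, Ighv3-8 had 2615 (in 3 cells) and 0, and Igkv8-23-1 had 3 and 128 (in 2 cells). There were 27 without day 10 mouse 1, and 199 and 6 without day 22 mice 1 and 2. Ighv1-12 was not called without day 22 mouse 2, Igkv8-23-1 without day 10 mouse 2 and Ighv3-8 without day 16 mouse 2 or either day 22 mouse. The count over the days ranged from 6 without day 16 mouse 2 to 855 without day 22 mouse 2, with 11 without day 16 mouse 1, 15 without day 10 mouse 2 and 682 without day 22 mouse 1. It was 5 with thinned cells, 695 with no filter, 191 without immunoglobulin genes and 247 with DESeq2's test.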

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

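The tests of the preMem share for the interferon genes, of droplets holding a PC and of RNA freed from plasma cells were chosen only after the results were seen, as were the tests of differences between days in the effects of zone and fraction and the comparison of germinal centre cells by well.

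In 33 groups of 6 mice, 4 held a mouse far from the others. The rule flags about 1 in 20 groups of independent, normally distributed values of 1 population. These groups pool mice of 3 days, some shares lie near 0, and shares of a fraction depend on each other. The 4 groups are thus not set against that rate. The share of prePC cells in the non-PC fraction was 1.65% in day 10 mouse 2, against 0 to 0.376% in the other mice. The share of PC in the non-PC fraction was 0% in day 22 mouse 2 (0 of 1164 cells, an upper limit of 3 counts), against 0.137% to 0.210% in the others. The others held only 1 or 2 such cells each, which that limit does not set apart from 0, so counting error may give this gap. The proliferating share of PC was 25% in day 16 mouse 1, against 57.1% to 75.0%. That mouse held few PC, 11 in the PC well and 1 in the other, so counting error is wide. The Ighe share of the PC fraction was 2.46% in day 10 mouse 2, where it was the most abundant constant gene of 3 of 164 cells, against 0 to 0.846%.

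The difference between LZ and DZ cells changed with day in 11 of 9390 genes (401 with an unadjusted p under 0.05), most of them immunoglobulin variable genes. The difference between the fractions changed with day in 107 of 9313 genes (1042 unadjusted), among them the secretion genes Ssr4, Hspa5 and Pdia4. The share of PC in the PC fraction was 83.1%, 23.0% and 53.7% on the 3 days. Without the cells not named PC the differences of Hspa5 and Ssr4 between days 16 and 10 in that fraction were 0.069 and 0.061, while Pdia4 kept its direction. For day 22 against day 10 alone the numbers were 7 and 1 (440 and 400 unadjusted).

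Memory genes stood higher in prePC cells than in germinal centre B cells, by a median of 2.60. Deeper prePC cells are argued against as the whole cause by the median after thinning, 2.39, and the mouse with most of the prePC cells by the median without it, 2.755. Droplets holding a PC and another B cell would carry at least 0.454 of the PC level of abundant PC genes, and 20 such genes stood at a median of 0.221 of it in prePC cells (0.143 to 0.298 over 5 mice). Without the 17 of 47 cells that reach the lowest level such a droplet needs, the memory median was 2.23 (20, 3 and 3 cells of 3 mice), so these are argued against as the whole cause, and single droplets among the 17 stay open (doublet scores called 1 of 10 prePC cells of the PC well, where their median of 0.0941 was the highest of any state, and 0 of 37 in the other). The unstated rule behind the annotation stays open, as 28 of the 47 cells were in the cluster holding most preMem cells, and no biological explanation was tested.

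Interferon genes were lower on day 22 than on day 10 in the non-PC fraction, by a median of −1.23. A smaller share of preMem cells is argued against as the whole cause by the medians within DZ cells, −1.23, and within LZ cells, −0.83. Fewer genes of the list were tested within each state than in the fraction. A part of that share in the change stays open, as the median within LZ cells was closer to no change. A single outlying mouse is argued against by the median closest to 0 when 1 mouse is left out, −0.97 (without day 10 mouse 2). A difference in the time of the response, which the design names, stays open and untested, since mice of a day may share more than the day, and the list kept no call with an estimated correlation (0 lists).

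Myc response genes were higher in germinal centre cells of the PC well than in those of the other, by a median of 0.91. Against cells drawn to the same mix of states the median was 0.0579, with 3 list genes and 293 of 6334 genes called, which is consistent with the larger share of LZtoDZ cells in the PC well. RNA freed from plasma cells is argued against as the cause: 21 of the 24 list genes stood above their level both in PC and in germinal centre cells of the other well in all 4 mice, which a mixture of these cannot give. A part of such RNA in other genes stays open, as the PC genes Hsp90b1 (0.99) and Ighg1 (0.36) were higher in these cells and Jchain (−0.12) and Mzb1 (−0.24) were not.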

How the results depend on the processing

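The comparison of germinal centre cells by well, the day effects within LZ and DZ cells and the prePC minimum were chosen only after the data were seen.

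Among 17 counts of called genes, 84 alternatives stayed within 1.5 times the reported count and 33 moved further; without 1 mouse, 74 stayed and 17 moved. Among 11 further counts, for pairs of days, 28 stayed and 32 moved; without 1 mouse, 31 stayed and 35 moved. Among 55 differences and trends of shares, 75 alternatives kept their direction and 11 reversed; without 1 mouse, 270 kept it and 20 reversed. The cause was not tested except where named.

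Thinning cells, which removes counts and shallow cells by construction, gave 1660 genes between the fractions, 223 for prePC against germinal centre cells, 435 for prePC against PC, 2187 between the zones, 287 for cycling PC, 2399 for DZ, 1468 for LZ, 2513 for LZtoDZ, 1812 for preMem, 605 for PC and 103 for LZ cells of the PC fraction, 580 between the wells, and over the days 5 in the PC fraction, 153 in LZ and 82 in DZ. DESeq2's test gave 411, 1606, 533, 2066 and 1102 genes for prePC against germinal centre cells, the zones, cycling PC, DZ and LZ, and over the days 247 in the PC fraction, 125 in LZ and 78 in DZ. No filter gave 1491 genes for prePC against PC, 597 for LZ cells of the PC fraction, and over the days 756 in the non-PC fraction (841 for day 22 against day 10), 695 in the PC fraction, 567 in LZ and 287 in DZ. Over the days in the PC fraction, leaving out immunoglobulin genes gave 191 and leaving out cells named against the fraction 4; the differences of Hspa5 and Ssr4 between days 16 and 10 then went from −1.43 and −1.69 to 0.069 and 0.061. Of the other alternatives for 205 values of named genes, 1372 kept direction and call, 40 lost the call, 3 gained it and 2, those of Hspa5 and Ssr4, reversed; without 1 mouse, 1029 kept both, 65 lost the call and 1 gained it. At least 30 cells per sum gave 1006 between the wells.

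Without the mouse block the paired comparisons stayed within 1.5 times their counts: 4294 genes between the fractions, 1090 for prePC against germinal centre cells, 1027 for prePC against PC, 2611 between the zones, 889 for cycling PC and 2061 between the wells.

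Leaving out 1 mouse gave ranges of 314 to 710 genes for prePC against germinal centre cells, 509 to 973 for prePC against PC, 332 to 945 for cycling PC and 67 to 490 for LZ cells of the PC fraction. Over the days they were 193 to 433 in the non-PC fraction (166 to 584 for day 22 against day 10, 57 to 277 for 16 against 10, 5 to 25 for 22 against 16), 6 to 855 in the PC fraction (2 to 199, 3 to 917 and 0 to 630 for the same pairs), 100 to 219 in LZ and 76 to 153 in DZ. Where a day was left with 1 mouse, that mouse is assumed to vary like the others.

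With all cells of the mouse as denominator the correlation of the preMem share of the PC fraction with day went from 0.256 to −0.108. The proliferating share of PC minus LZ went from −19.3 to 3.02 points by the deposited phase, that of PC minus preMem from −0.0209 to 10.1 without thinning, 40.5 by phase and −21.8 by the G2 and M phase list, and that of prePC minus PC from −1.38 to 5.13 by the G2 and M phase list. Its correlation with day went from 0.116 to −0.495 without thinning and −0.777 by phase in germinal centre cells, and from 0.190 to −0.384 and −0.860 in LZ. Counting each cell once turned Ighd between the fractions from −1.38 to 2.56 points and the correlation of Ighg3 with day in the PC fraction from −0.171 to 0.755.

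Without 1 mouse, correlations with day ranged from −0.165 to 0.818 (LZ) and −0.708 to 0.0197 (prePC) in the non-PC fraction, −0.0840 to 0.524 (preMem) and −0.802 to 0.324 (prePC) in the PC fraction, and for the proliferating share −0.0200 to 0.736 in PC, −0.570 to 0.459 in germinal centre cells and −0.226 to 0.741 in LZ. For Ighg3 in the PC fraction the range was −0.666 to 0.201, and for Ighe in the non-PC fraction −0.381 to 0.507. Differences in points ranged from −3.37 to 1.97 (PC minus preMem, proliferating), −3.51 to 1.03 (prePC minus PC, proliferating) and −0.115 to 0.416 (Ighe, PC minus non-PC fraction).

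With an estimated correlation the lists called went from 16 to 0 between the fractions (14 to 7 without cells named against them), 13 to 0 and 10 to 0 for prePC against germinal centre cells and PC, 16 to 2 between the zones, 13 to 0 for cycling PC, 17 to 4 for DZ, 20 to 0 for LZ, 16 to 0 for LZtoDZ, 19 to 8 for preMem, 19 to 0 for PC and 15 to 0 for LZ cells of the PC fraction, 12 to 0 between the wells and 13 to 0 for day 22 against day 10.

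Not run were 30 cells per sum for prePC, cycling PC and the states of the PC fraction, where too few sums remain, and the alternatives for receptor mutation and clones, whose data were not used here. Leaving out cells under 1000 UMIs moves nothing, since 0 cells are that shallow. Small changes were mostly missed for prePC against germinal centre cells and for the days of the PC fraction. There 10 of 100 and 6 of 100 simulated changes of 2-fold were called, against 61 of 99 for prePC against PC. Depth was not varied in these simulations, so the cause was not tested.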

Other observations

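The comparisons of germinal centre cells by well and of prePC cells with each state were chosen only after the data were seen.

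Swapping the 2 sums within mice in all 32 ways gave fewer genes than the real grouping for the fractions (3454 genes, highest other 2) and the zones (3373, 2). The same held for DZ (3765, 0), LZ (2601, 2), LZtoDZ (4593, 2) and preMem (3171, 75). The fractions were sorted by cell type, and the states named by an unstated rule that may use the same counts. The real grouping could thus hardly fail to give the most genes, so no conclusion on chance is drawn from the swaps. For the other comparisons the swaps are too few for a share under 0.05: prePC against germinal centre cells (729, highest other 186) and against PC (898, 0), PC (1826, 0) and LZ cells (373, 0) of the PC fraction, cycling PC (1010, 1) and the wells (1893, 2).

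After thinning, the share of cells with an eYFP UMI was 66.1% in DZ, 65.3% in LZ, 61.4% in LZtoDZ, 51.1% in preMem, 40.9% in prePC and 33.3% in PC. Immunoglobulin genes took 22.1% of the UMIs of PC and 2.76% of those of prePC cells. Of 2229 genes, 4 were higher in prePC cells than in each of the 5 other states: Plac8, Gpx1, Rpl22l1 and Rps12.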
